A study of Mus musculus with 6 samples.

How the data were processed

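Gene expression was measured on 6 single-colour Affymetrix arrays, 3 from Rb-null and 3 from control mice, in bone marrow cells sorted for CD71 and Ter-119. Per the labels, total RNA was extracted with Trizol and QIAGEN columns and labelled with biotin. The deposited values are intensities per probe set on a linear scale, never negative. The method that made them from the scans, and any scaling between arrays, is not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and no per-sample column was left unused.

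Of 45101 probe sets, 64 control probe sets, 4 that were empty on every array and 1 of Ptprj with a value of 20200000 on Rb-null replicate 3, above the range of a 16-bit scanner, were left out. This left 45032, of which 34941 carried 1 gene symbol, 932 carried several and 9159 had none. Values were transformed as log2(value + 16). Array medians then differed by up to 0.264, more than the limit of 0.2 set for keeping the deposited scaling, so the arrays were quantile normalized. Probe sets with a mean above the 40th percentile (log2 5.12, an intensity of 18.9) were kept, and each gene was represented by its probe set with the highest mean, giving 13232 tested genes out of 18192 on the array. Of 5415 genes with more than 1 probe set past the filter, 46.2% had probe sets of opposite sign, as did 12 of 62 such named genes, Anxa1, Bcl2l1, Becn1, H2-Ab1, Hbb-bh1, Il2rb, Nrf1, Ppara, Rbl1, Tyms, Uros and Xaf1. The 4780 probe sets without a gene name that passed the filter were fitted separately, and limma called 0 of them (lowest adjusted p = 0.612, 174 at unadjusted p under 0.05; with the replicate block 0, lowest adjusted p = 0.0752, 558 at unadjusted p under 0.05).

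Rb-null was compared with control in R 4.3.3 with limma 3.58.1, by the 2-sided moderated test with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are Rb-null over control, and SE is the standard error of the fit without the replicate block. It takes no account of arrays sharing a replicate number. With the block the SE differs, as for Rb1 (0.16 against 0.31) and Epor (1.08 against 0.90). An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so single genes were tested by limma alone. Gene lists were tested with limma's camera, 2-sided, with a preset correlation of 0.01 between genes and adjustment over 26 lists. Camera with an estimated correlation and limma's fry were run beside it, and every adjusted p of a list comes from these functions.

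The comparison, the tests, the lists and the rule for naming genes were fixed before the data were examined. The 26 tested lists were E2F targets and DNA replication, mitosis, cyclin-dependent kinase inhibitors and cycle exit, p53 targets, oxidative phosphorylation subunits, regulators of mitochondrial biogenesis, the tricarboxylic acid cycle, mitochondrial fatty acid oxidation, mitochondrial ribosome and import, heme and iron, globins, erythroid transcription factors and signalling, red cell membrane, early erythroid and progenitor genes, autophagy, apoptosis, glycolysis and hypoxia, cytosolic ribosomal proteins, interferon-stimulated genes, immediate early and heat shock genes, and markers of granulocytes, macrophages, B cells, T and NK cells, megakaryocytes, and mast cells with basophils and eosinophils. Sex-linked genes were read per array without a test. Named genes were a fixed set of cell cycle, mitochondrial and erythroid regulators with Rb1, up to 10 passing genes in each direction whose groups do not overlap or, as none passed, the 5 with the smallest p in each direction, and up to 4 members of each list with the smallest p.

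Whether replicate numbers pair the arrays was checked on each array's deviations from its group mean. Arrays of the same number correlated at 0.636, 0.615 and 0.653 across genes, and the highest correlation with an array of another number was 0.0370, so pairs are given beside the results and the number was also used as a block. Genes are not independent replicates, and what the numbers stand for is not given in the sources used here.

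Both fits were tested on 20 simulated data sets of 13232 genes with 200 changed. Without the block 31.8% of 4-fold changes and 0.05% of 2-fold changes were recovered, and with it 99.65% and 79.1%, with 8.80% of the called genes false. The simulated data were built from the fit with the block, with its differences between replicate numbers and its residual spread. An advantage of the block was therefore built in, and these rates hold only if the arrays follow that model. Camera, run with the block, recovered a list shifted by -0.3 in 20 of 20 simulations and called 1 of 480 unshifted lists. Those genes were simulated without correlation, whereas the estimated correlation in the oxidative phosphorylation list was 0.216. The main calls come from camera without the block, so these rates need not hold for them. Alternatives covered normalization, offsets of 1 and 64, the filter, the choice of probe set, the variance model, array weights, the block, leaving out each array, and the correlation between genes. A further 3 were chosen after seeing the data: leaving out both arrays numbered 3, the mean granulocyte marker level as a covariate, and the block with a variance trend and robust moderation. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws.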

Results

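Expression was measured in bone marrow cells sorted for CD71, the transferrin receptor, and Ter-119, an antigen of the red cell lineage, a combination that marks nucleated erythroid precursors. RNA from these cells was read on 6 Affymetrix mouse arrays, 3 labelled Rb-null and 3 labelled control. Rb-null mice carried floxed Rb1 on both alleles and a Cre recombinase at the erythropoietin receptor locus, while controls carried the same Cre and a single floxed allele, per the design text. The series title names the question as how Rb, the retinoblastoma protein that restrains entry into S phase, ties leaving the cell cycle to the making of mitochondria during erythropoiesis. Nothing in the labels says whether arrays of the same group come from separate animals, so p-values measure the spread between these samples, which may be technical.

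The median deposited intensity lay between 23.3 and 31.2 on the 6 arrays, and the number of arrays limits the precision of every value. Both arrays numbered 3 stood apart. Their 18S ribosomal RNA control probe sets averaged 1231 (control) and 542 (Rb-null), against 32.6 to 66.2 on the other 4 arrays. The first principal component, with 51.3% of the variance, set these 2 arrays apart, and on the second, with 21.8%, the Rb-null array of each number lay below the control array. The ratio of actin signal at the 3' to that at the 5' end was 1.67, 1.15 and 1.18 on control arrays 1, 2 and 3 and 1.43, 1.10 and 1.01 on the Rb-null arrays, lower in each pair, while that of Gapdh was lower in pair 3 only. S100a8, an abundant protein of granulocytes, read 9111 to 12488 on the 6 arrays and was the brightest probe set on 3 of them.

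**Figure D1:**
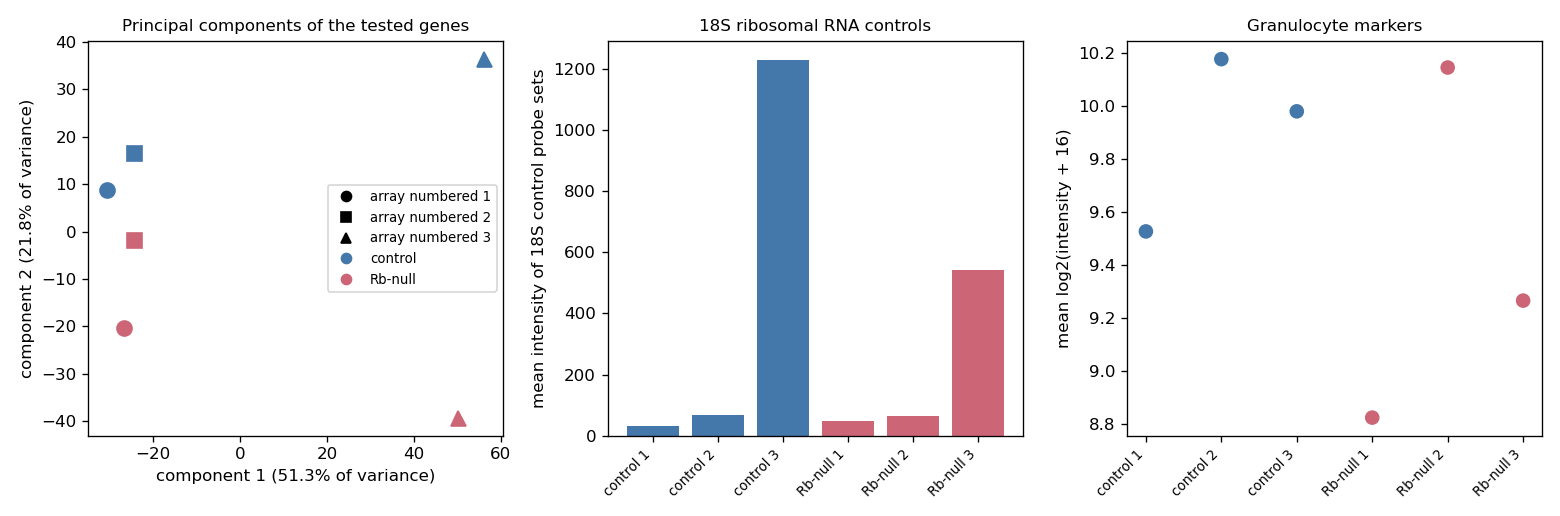
Left, the 6 arrays on the first 2 principal components of the tested genes (percent of variance on the axes); middle, mean deposited intensity of the 18S control probe sets; right, mean log2(intensity + 16) of the granulocyte markers on each array. Blue stands for control and red for Rb-null; the 18S values of the arrays numbered 3, 1231 and 542, stand above the 32.6 to 66.2 of the other 4.

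Rb1, the gene floxed in this model, gave signal in all samples. Its bright probe set read 2760, 2152 and 1379 on control arrays 1, 2 and 3, and 4045, 3670 and 2897 on Rb-null arrays 1, 2 and 3. The means were 2097 ± 692 (SD, n = 3) and 3537 ± 585 (SD, n = 3), a log2 fold change of 0.75 (SE 0.31), higher in each of the 3 pairs and not past the limma test (adjusted p = 1.00). A second Rb1 probe set read at most 24.8 on any array. Where either probe set lies relative to the floxed part of the gene is not given in the sources used here, so Rb1 signal does not check the labels, and every direction below rests on the labels alone.

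Between Rb-null and control cells, genes of mitochondrial energy production were lower as groups, and targets of p53 and of the cell cycle machinery were higher as groups. The subunits of oxidative phosphorylation had a median log2 fold change of -0.47 over 79 genes, and p53 targets a median of 0.39 over 28 genes. Among single genes the lowest p-values belonged to the transcription factor Klf5, with 6.18-fold higher signal in Rb-null cells, and the stress-induced regulator Ddit3, with 4.44-fold higher signal. Of 26 gene lists tested with camera at a preset correlation, 6 rose and 10 fell, granulocyte markers among the latter (median -0.52), while no single gene passed the test over all genes. With an estimated correlation camera called 0 of the 26 lists (lowest adjusted p = 0.312).

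Klf5 read 171 ± 63.6 (SD, n = 3) in controls and 1129 ± 170 (SD, n = 3) in Rb-null cells, a log2 fold change of 2.63 (SE 0.28). Ddit3, the CHOP transcription factor of the integrated stress response, read 217 ± 54.5 (SD, n = 3) and 1028 ± 35.9 (SD, n = 3). Irs2, an adaptor of insulin signalling, had a log2 fold change of 1.86 (SE 0.27), the deubiquitinase Otud1 2.60 (SE 0.37), and Ddit4, an inhibitor of mTOR signalling, 2.60 (SE 0.38). On the other side stood Aldh1a1, a retinaldehyde dehydrogenase, at -1.55 (SE 0.26), the guanine deaminase Gda at -1.77 (SE 0.33) and Prxl2a at -1.49 (SE 0.27). Rec114 had -2.34 (SE 0.43) and the uncharacterised transcript 1700016C15Rik -2.36 (SE 0.43). The Rb-null mean of 1700016C15Rik, log2 4.35, lay below the filter value of 5.12, so the size of its fall is uncertain. Across the alternatives it ran from -2.74 to -1.17. All 10 had the same sign in each of the 3 pairs, and their Rb-null and control values did not overlap. As these genes were picked by their p on the same arrays, this adds no support. None of them passed limma's test, with adjusted p from 0.106 for Klf5 to 0.315 for Rec114. Klf5 and Ddit3 did pass limma's test with an offset of 64 (adjusted p = 0.0280). With array weights they passed again, and Otud1 too (limma adjusted p from 0.0230 to 0.0269). A second Klf5 probe set past the filter had a log2 fold change of 0.14 (SE 0.42), so the Klf5 probe sets disagree.

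Over the 13232 genes tested, limma called 0 genes at adjusted p under 0.05, and 537 had an unadjusted p under 0.05 (337 higher and 200 lower), against 661.6 by chance for exchangeable arrays. With the replicate number as a block, 0 genes again passed (lowest adjusted p = 0.0844), 144 stood under 0.1 (112 higher and 32 lower), and 2237 had an unadjusted p under 0.05. The groups did not overlap for 1312 genes, 9.92% of those tested, where chance gives 10% if the arrays are exchangeable. Arrays of the same number resemble each other, and the other 3 splits that part every pair gave 318 to 373 such genes and 42 to 70 at unadjusted p under 0.05. A fit with the block and a variance trend with robust moderation, chosen after seeing the data, called 473 genes (289 higher and 184 lower). Of the genes called by that trend and robust fit, 9.80% were false in simulated data, above the nominal level. Those data had independent genes and were built from the fit with the block, so the share need not hold here.

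**Figure D2:**
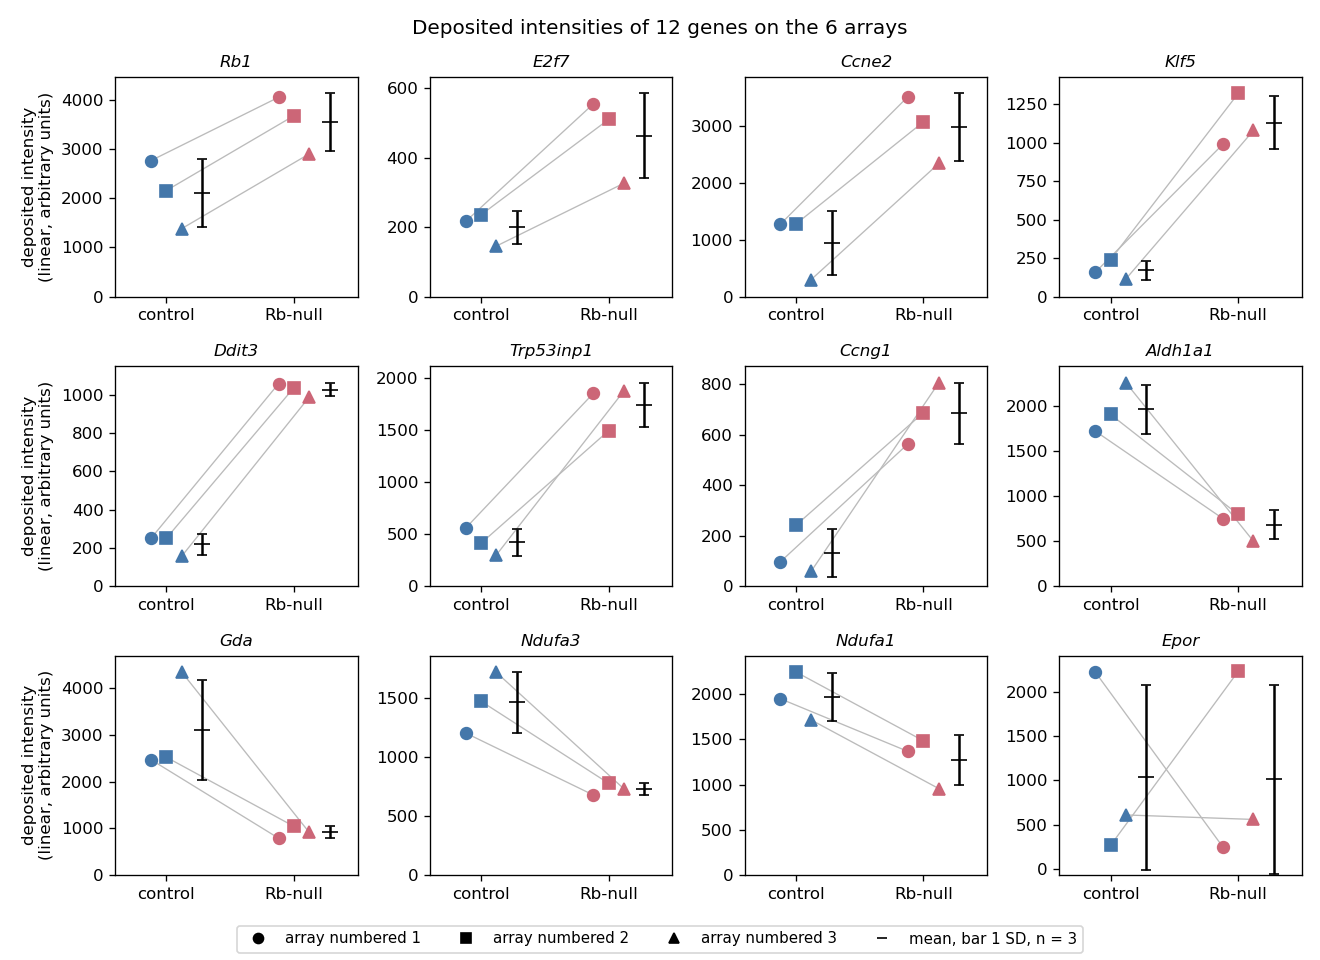
Deposited intensity (linear, arbitrary units) of 12 genes on each array, with lines joining arrays of the same number and bars showing the mean and 1 SD (n = 3). Rb1 reads 1379 to 2760 on control and 2897 to 4045 on Rb-null arrays, Epor differs in sign between the pairs, and none of the 12 genes passed limma's test over all genes.

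Cell cycle genes were shifted upward as groups. The list of E2F targets and DNA replication genes rose, with a median log2 fold change of 0.18 over 69 genes, 48 of them positive (camera adjusted p = 1.1e-05, but adjusted p = 0.435 with an estimated correlation). Its pair medians were 0.24, 0.04 and 0.42 for pairs 1, 2 and 3. None of its genes passed when adjusted over the list alone, and 5 did with the block. Without control replicate 3 its call was lost (median 0.07). The E2F family members E2f7 and E2f8, repressors that are themselves E2F targets, had log2 fold changes of 1.12 (SE 0.26) and 0.76 (SE 0.32). Cyclin E2, Ccne2, read 948 ± 562 (SD, n = 3) in controls and 2970 ± 593 (SD, n = 3) in Rb-null cells, and cyclin E1, Ccne1, had a log2 fold change of 0.64 (SE 0.36). Tyms, thymidylate synthase, and Slbp, which binds histone mRNA, each had 1.02 (SE 0.26 and 0.33). The other Tyms probe sets past the filter had 0.42 (SE 0.34) and -0.18 (SE 0.29). E2f1 had 0.26 (SE 0.26), and its other probe sets past the filter, looked at after its values were seen, 0.93 (SE 0.24) and 0.52 (SE 0.67). Among the other members were E2f2 at 0.13 (SE 0.25), E2f3 at -0.48 (SE 0.52) and E2f4 at 0.04 (SE 0.38). The related pocket proteins Rbl1 and Rbl2 had -0.06 (SE 0.53) and -0.15 (SE 0.31).

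Mitosis genes rose as a list, with a median log2 fold change of 0.21 over 62 genes, 48 of them positive (camera adjusted p = 4.1e-05; adjusted p = 0.435 with an estimated correlation). Of these, 0 passed when adjusted over the list alone and 1 with the block, and the call was lost without control replicate 3 or without Rb-null replicate 1 (medians 0.08 and 0.07). Fbxo5, the inhibitor of the anaphase-promoting complex, had 1.02 (SE 0.25), Ndc80 0.69 (SE 0.29) and Ube2c 0.70 (SE 0.33), while the phosphatase Cdc25b had -0.76 (SE 0.25). The list of cyclin-dependent kinase inhibitors and exit from the cycle rose as well (median 0.14 over 28 genes, camera adjusted p = 0.0054; adjusted p = 0.333 with an estimated correlation), though its pair 3 median was -0.01 and its call was lost without Rb-null replicate 2 (median 0.10). Its median ranged from 0.07 without Rb-null replicate 1 to 0.30 without both arrays numbered 3, a setting chosen after seeing the data. When adjusted over the list alone 2 of its genes passed, cyclin G1 (Ccng1) and the Myc antagonist Mxi1 at 1.20 (SE 0.27), and 6 passed with the block. Among named members, Cdk2, which drives S phase, had 0.93 (SE 0.27) and the inhibitor Cdkn2c 0.71 (SE 0.27), so the list holds both inhibitors and drivers. Cdkn1b, the p27 inhibitor, had 0.21 (SE 0.28). Cdkn1a, the p21 inhibitor, had 0.43 (SE 0.42) on the probe set with the higher mean log2 value, and 0.06 without Rb-null replicate 1. Without control replicate 3 the other probe set had the higher mean and took its place, at 1.61. In the full fit that other probe set, singled out after its values were seen, had 1.66 (SE 0.25). Their intensities were close, 137 in controls and 207 in Rb-null cells against 75.3 and 273.

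Targets of p53, the tumour suppressor that halts or kills stressed cells, rose as a list (median log2 fold change 0.39 over 28 genes, 19 positive, camera adjusted p = 3.3e-07; adjusted p = 0.312 with an estimated correlation). Pair medians were 0.46, 0.25 and 0.42. When adjusted over the list alone, 6 genes rose, Ddit4, Trp53inp1, Ccng1, Phlda3, Bbc3 and Mdm2, and 9 with the block, whereas 0 passed over all genes. Some of these genes are not particular to this list. Ccng1 is also in the cycle exit list, Bbc3 in the apoptosis list and Ddit4 in the glycolysis and hypoxia list. Ddit4 also belongs to the stress response set picked by hand below, so the rises of these groups are not independent. Trp53inp1 read 421 ± 130 (SD, n = 3) in controls and 1740 ± 215 (SD, n = 3) in Rb-null cells, and Ccng1 had a log2 fold change of 2.42 (SE 0.42). Phlda3 had a log2 fold change of 1.58 (SE 0.37), Bbc3, the pro-apoptotic protein PUMA, 1.81 (SE 0.53), and Mdm2, the ligase that degrades p53, 0.97 (SE 0.29). The wider apoptosis list was not called (camera adjusted p = 0.998, median -0.11, 1 gene past the list alone with the block), with Bcl2l11 at 0.89 (SE 0.32) and the survival factor Bcl2l1 at -0.71 (SE 0.42).

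Mitochondrial genes moved the other way. The oxidative phosphorylation list fell, with 73 of 79 genes negative and 66 lower in each of the 3 pairs (camera adjusted p = 4.2e-14; adjusted p = 0.414 with an estimated correlation). Pair medians were -0.36, -0.45 and -0.55. When adjusted over the list alone 0 genes passed, and 39 did with the block, all of them lower. The complex I subunit Ndufa3 read 1466 ± 257 (SD, n = 3) in controls and 730 ± 49.6 (SD, n = 3) in Rb-null cells, and its partners Ndufs1, Ndufa1 and Ndufs5 had log2 fold changes of -0.94 (SE 0.30), -0.71 (SE 0.25) and -0.77 (SE 0.29). Granulocyte markers had a median of -0.52 beside this (pair medians -0.76, -0.03 and -0.72), the actin end ratio was lower in each pair, and with the granulocyte level as a covariate, chosen after seeing the data, the oxidative phosphorylation list was still called, with a median of -0.30.

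The mitochondrial ribosome and protein import list fell (median -0.33 over 96 genes, 84 negative, camera adjusted p = 1.0e-06; adjusted p = 0.435 with an estimated correlation), with Mrps21 at -0.77 (SE 0.26), Mrpl52 at -0.87 (SE 0.30) and Timm8b at -1.12 (SE 0.43). Genes of the tricarboxylic acid cycle fell (median -0.33 over 30 genes, 25 negative, camera adjusted p = 5.9e-04; adjusted p = 0.435 with an estimated correlation), among them fumarase, Fh1, at -0.71 (SE 0.31), Sdha at -0.69 (SE 0.31) and citrate synthase, Cs, at -0.58 (SE 0.27). Mitochondrial fatty acid oxidation genes fell (median -0.33 over 20 genes, camera adjusted p = 0.0089; adjusted p = 0.435 with an estimated correlation), with Ech1 at -1.63 (SE 0.78), Acaa2 at -0.89 (SE 0.47) and Eci2 at -0.62 (SE 0.33). The other Acaa2 probe sets past the filter had -0.02 and -0.19. Ech1 was dim in Rb-null cells, with a mean of log2 5.47 near the filter value of 5.12. Across the alternatives it ran from -2.41 to -0.55. In these 3 lists 0 genes passed when adjusted over the list alone, and with the block 1 did, in the fatty acid list. With the granulocyte covariate the mitochondrial ribosome list was nearer 0 (median -0.18, camera adjusted p = 0.0347) and the tricarboxylic acid and fatty acid lists lost their calls (medians -0.16 and -0.25, camera adjusted p = 0.180 and 0.213), as both did without control replicate 2 (medians -0.24 and -0.29) and without Rb-null replicate 3 (medians -0.16 and -0.23).

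The regulators of mitochondrial biogenesis were not called as a list (median -0.04 over 29 genes, camera adjusted p = 0.539). Tfam, which packages mitochondrial DNA, had a log2 fold change of 0.11 (SE 0.25). Nrf1, a transcription factor for respiratory genes, had -0.02 (SE 0.25) on the probe set with the highest mean. Its other probe sets past the filter had 0.22 (SE 0.26), 0.46 (SE 0.31) and 0.76 (SE 0.31), so the Nrf1 probe sets disagree. The deacetylase Sirt1 had 1.38 (SE 0.39), Yy1 0.80 (SE 0.36), Sp1 0.71 (SE 0.41) and Ppara -0.59 (SE 0.36), and 1 gene of the list passed when adjusted over the list alone with the block. The coactivators Ppargc1a and Ppargc1b and the receptor Esrra were below the filter, with deposited intensities of at most 32.2 for Ppargc1a, 10.8 for Ppargc1b and 26.3 for Esrra. Autophagy and mitochondrial clearance genes fell as a list (median -0.20 over 31 genes, camera adjusted p = 0.0478; adjusted p = 0.435 with an estimated correlation), with Atg4a at -0.99 (SE 0.35), Becn1, the beclin of autophagosome formation, at -0.82 (SE 0.31), Gabarapl2 at -0.66 (SE 0.40) and Nbr1 at -0.44 (SE 0.26). That call was lost under 13 of 21 alternatives, among them 5 of the 6 fits with 1 array left out.

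**Figure D3:**
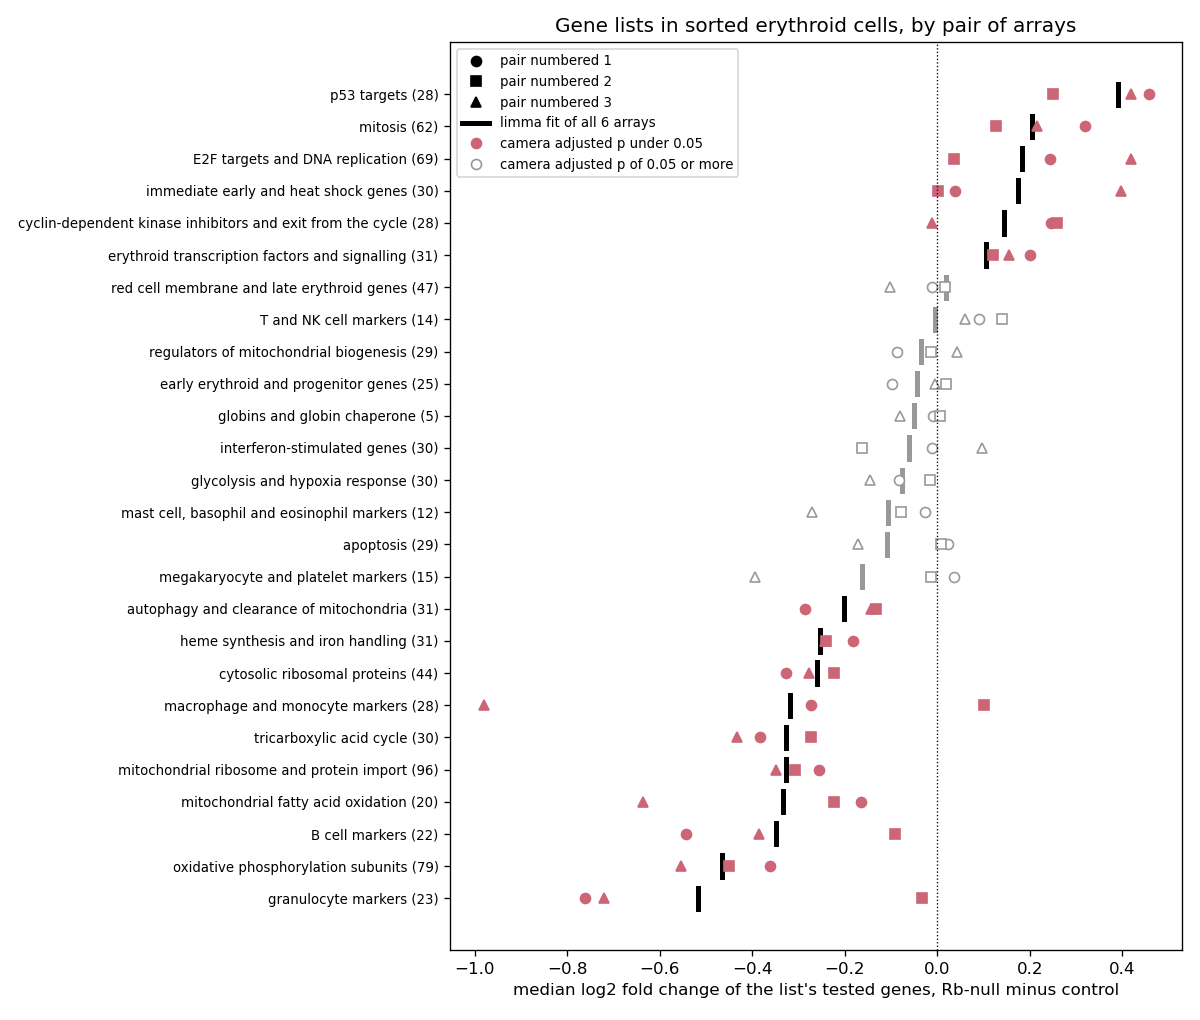
Median log2 fold change (Rb-null minus control) of the 26 gene lists, number of tested genes in brackets. Symbols give each pair of same-numbered arrays, bars the limma fit of the 6 arrays, and filled symbols the 16 lists called by camera with a preset correlation, from granulocyte markers at -0.52 to p53 targets at 0.39.

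Erythroid genes did not move together. Erythroid transcription factors and signalling genes rose as a list (median 0.10 over 31 genes, 20 positive, camera adjusted p = 0.0084; adjusted p = 0.402 with an estimated correlation), and 1 gene passed when adjusted over the list alone, Nr3c1, the glucocorticoid receptor, at 1.27 (SE 0.28). With the block 7 genes passed within the list, 6 higher and 1 lower, and the call was lost without control replicate 1 or Rb-null replicate 2 (medians 0.05 and 0.18), while without Rb-null replicate 3 the median was -0.01. Klf1, a master regulator of globin genes, had 0.45 (SE 0.29), Lyl1 0.87 (SE 0.25), Mafg 0.91 (SE 0.28), Hdac6 0.89 (SE 0.27) and Gata1 0.06 (SE 0.28). Epor, the erythropoietin receptor whose locus carries the Cre, had -0.14 (SE 0.90), with pair differences of -3.24, 2.96 and -0.14. Heme synthesis and iron handling genes fell (median -0.25 over 31 genes, 24 negative, camera adjusted p = 0.0074; adjusted p = 0.414 with an estimated correlation), with Nfs1 at -0.69 (SE 0.36), Hebp1 at -0.90 (SE 0.48), Iscu at -0.72 (SE 0.39), Uros at -0.41 (SE 0.29) and Tfrc, which encodes CD71, at 0.09 (SE 0.25). No gene of that list passed when adjusted over the list alone, with or without the block, and its call was lost with the granulocyte covariate (median -0.15, camera adjusted p = 0.180) and without control replicate 2 or Rb-null replicate 3 (medians -0.20 and -0.17).

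Globins and their chaperone were not called (5 genes, median -0.05, camera adjusted p = 0.998). Among them were Hba-a2 at 0.94 (SE 0.69), Hbb-bh1 at -0.65 (SE 0.49), Hba-x at -0.09 (SE 0.27) and Hbb-y at 0.10 (SE 0.45). Of 10 listed members, 6 had a probe set with 1 gene symbol and 5 were tested. The result therefore does not cover globin expression as a whole. The red cell membrane and late erythroid genes were not called (47 genes, median 0.02, camera adjusted p = 0.717), with the integrin Itga4 at -0.95 (SE 0.26), catalase, Cat, at -1.36 (SE 0.39), Bpgm, which makes 2,3-bisphosphoglycerate, at -0.81 (SE 0.33) and Cd36 at -0.99 (SE 0.43), and 3 genes passed within the list with the block, all lower. Early erythroid and progenitor genes were not called (25 genes, median -0.04, camera adjusted p = 0.717), with the nucleolar proteins Nop56 at 0.79 (SE 0.29), Ncl at 0.50 (SE 0.27) and Fbl at -0.37 (SE 0.40), and Cd48 at -0.48 (SE 0.47).

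Cytosolic ribosomal protein genes fell, with 43 of 44 genes negative and a median of -0.26 (camera adjusted p = 2.4e-05; adjusted p = 0.435 with an estimated correlation). Rpl37 had -0.71 (SE 0.31), Rpl35 -0.52 (SE 0.26), Rpl10a -0.51 (SE 0.31) and Rps14 -0.46 (SE 0.25), and 0 genes passed when adjusted over the list alone, with or without the block. The granulocyte covariate ended this call (median -0.12, camera adjusted p = 0.162). Immediate early and heat shock genes rose as a list (median 0.17 over 30 genes, camera adjusted p = 0.0466; adjusted p = 0.435 with an estimated correlation), although pairs 1 and 2 had medians of 0.04 and 0.00264 against 0.40 in pair 3. Its call was lost without control replicate 3 or Rb-null replicate 1 (medians 0.05 and 0.09), with the granulocyte covariate (median -0.02) and under 6 further alternatives besides the estimated correlation. The chaperones Dnajb1, Hsp90aa1 and Hspa8 had 1.26 (SE 0.32), 0.94 (SE 0.36) and 0.66 (SE 0.31), while the immediate early gene Nr4a1 had -0.54 (SE 0.25), and without both arrays numbered 3, a setting chosen after seeing the data, the list median was -0.03. Of its genes 0 passed when adjusted over the list alone and 1 with the block. Glycolysis and hypoxia genes were not called (30 genes, median -0.08, camera adjusted p = 0.998), with Ddit4 past the list alone, Kdm3a at 0.93 (SE 0.38), Hk2 at -0.61 (SE 0.34) and Pfkfb4 at -0.43 (SE 0.25). Interferon-stimulated genes were not called (30 genes, median -0.06, camera adjusted p = 0.598, 1 gene past the list alone with the block), with Usp18 at 0.78 (SE 0.30), Irf9 at 0.74 (SE 0.30), Ifitm3 at -0.61 (SE 0.28) and Xaf1 at -0.94 (SE 0.42).

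Markers of cells outside the erythroid lineage were mostly lower. Granulocyte markers fell as a list, with 22 of 23 genes negative and a median of -0.52 (camera adjusted p = 6.9e-05; adjusted p = 0.435 with an estimated correlation), and pair medians of -0.76, -0.03 and -0.72. Cybb, a subunit of the phagocyte oxidase, had -1.18 (SE 0.54), Chil3 -0.73 (SE 0.44), Fcnb -0.69 (SE 0.37) and Anxa1 -0.60 (SE 0.32). Macrophage and monocyte markers fell (median -0.32 over 28 genes, camera adjusted p = 0.0084; adjusted p = 0.490 with an estimated correlation), with pair medians of -0.27, 0.10 and -0.98 and with Vcam1 at -1.01 (SE 0.59), Mpeg1 at -0.76 (SE 0.47), Ctss at -0.69 (SE 0.41) and Fcgr3 at -0.65 (SE 0.38). B cell markers fell (median -0.35 over 22 genes, camera adjusted p = 0.0015; adjusted p = 0.435 with an estimated correlation), with Cd79b at -1.09 (SE 0.44), the class II gene H2-Ab1 at -1.09 (SE 0.46), H2-Eb1 at -0.83 (SE 0.30) and Ms4a1 at -0.68 (SE 0.29). In these 3 lists 0 genes passed when adjusted over the list alone, and with the block 7 B cell markers did. The macrophage call was lost without control replicate 3 (median -0.03), and all 3 calls were lost without Rb-null replicate 1 (medians -0.07, -0.17 and -0.09).

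Markers of T and NK cells were not called (14 genes, median -0.01, camera adjusted p = 0.399), with Gzmb at 0.56 (SE 0.27), Cd5 at 0.49 (SE 0.33), Thy1 at 0.43 (SE 0.25) and Il2rb at -0.58 (SE 0.45). Megakaryocyte and platelet markers were not called (15 genes, median -0.16, camera adjusted p = 0.303), with Vwf at -0.47 (SE 0.27), Cd9 at -0.46 (SE 0.36), Gp9 at -0.34 (SE 0.33) and Gp5 at 0.31 (SE 0.33). Mast cell, basophil and eosinophil markers were not called (12 genes, median -0.11, camera adjusted p = 0.303), with Srgn at -0.85 (SE 0.43), Hdc at -0.75 (SE 0.33), Epx at -0.67 (SE 0.62) and Mcpt4 at 0.24 (SE 0.26).

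The 4 lists of oxidative phosphorylation, mitochondrial ribosome and import, cytosolic ribosomal proteins and p53 targets kept their calls in each of the 6 fits with 1 array left out. Their medians then ran from -0.59 to -0.35, from -0.44 to -0.19, from -0.44 to -0.17 and from 0.25 to 0.41 in that order. The p53 median was 0.25 without Rb-null replicate 3. Without control replicate 2 the mitochondrial ribosome and cytosolic ribosomal protein medians were -0.19 and -0.17, with camera adjusted p = 0.0267 and 0.0489, and without Rb-null replicate 2 the latter was -0.44. No list was called by camera with an estimated correlation, and fry, which tests a list on its own, called 0 lists without the block (lowest adjusted p = 0.115) and 1 with it, the erythroid transcription factors (adjusted p = 0.0439). In 5 uncalled lists the median and camera's direction differed in sign, those of regulators of mitochondrial biogenesis, red cell membrane genes, progenitor genes, globins and T and NK cells.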

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

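Leaving out both arrays numbered 3, the granulocyte covariate, and the block with a variance trend and robust moderation were chosen after the results were seen. Under the alternatives tried, oxidative phosphorylation, mitochondrial ribosome and import, and p53 targets kept their direction and call except with an estimated correlation, though each moved by over 1.5 times under some of them. For the changes below the cause was not tested, except that a fit with fewer arrays has less data.

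With the replicate number as a block, limma passed 0 genes (lowest adjusted p = 0.0844), and 2237 had an unadjusted p under 0.05 against 537 without it. The block left the 16 camera calls as they were. Within lists it raised the genes passing over the list alone, as in oxidative phosphorylation from 0 to 39, E2F targets from 0 to 5, B cell markers from 0 to 7 and p53 targets from 6 to 9, and fry called 1 list with it and 0 without. With it and a variance trend and robust moderation, limma passed 473 genes (289 up, 184 down), Rb1 among them at 0.75 (limma adjusted p = 0.0237, 0.136 with the block alone and up to 1.00 under the other alternatives). An offset of 64 called 2 genes, Klf5 and Ddit3, and array weights 3, Klf5, Ddit3 and Otud1, all up.

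In this paragraph, autophagy, immediate early and heat shock genes and macrophage markers are given where their camera call was lost. All other values are given because their sign changed. Without quantile normalization Nrf1 was 0.00201, globins 0.00914, T and NK markers 0.0134 and autophagy -0.178, and with arrays centred on their medians these were 0.00252, 0.00966, 0.0139 and -0.178. With an offset of 1 autophagy was -0.206, immediate early and heat shock genes 0.198 and T and NK markers 0.135. Immediate early and heat shock genes were 0.0924 with an offset of 64 and 0.12 without a filter, where T and NK markers were 0.0170. A strict filter gave globins 0.0225 and autophagy -0.223. The mean of all probe sets gave Rbl1 0.0425, Nrf1 0.357, regulators of mitochondrial biogenesis 0.0324, red cell membrane -0.00334, autophagy -0.111, apoptosis 0.00958 and T and NK markers 0.0142. Without probe sets ending in _x_at, _s_at or _a_at, red cell membrane was -0.0316, autophagy -0.216, immediate early and heat shock 0.175 and T and NK markers 0.0831. Array weights gave E2f4 -0.0444, Nrf1 0.0283, immediate early and heat shock 0.0173, macrophage markers -0.149 and megakaryocyte markers 0.0310.

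Without both arrays numbered 3, Gata1 was -0.00489, E2f4 -0.0403, Nrf1 0.0354, Il2rb 0.0826, regulators of mitochondrial biogenesis 0.00243, fatty acid oxidation -0.200, immediate early and heat shock -0.0323, macrophage markers -0.0757 and megakaryocyte markers 0.0483. Of these, fatty acid oxidation and macrophage markers lost their call, and the rest changed sign. With the granulocyte covariate, Rbl2 was 0.0886, Epor 0.255, Hba-x 0.0202, Hbb-y -0.242, Cd48 0.0841, Fbl 0.138, red cell membrane -0.0226, progenitor genes 0.0424, glycolysis 0.0438 and immediate early and heat shock -0.0244. The lists that lost their call with it were immediate early and heat shock genes, the tricarboxylic acid cycle (-0.159), fatty acid oxidation (-0.252), heme and iron (-0.149), autophagy (-0.114), cytosolic ribosomal proteins (-0.119) and macrophage (-0.0875) and B cell markers (-0.125). Granulocyte markers (-0.00936) lost theirs by construction, as the covariate is their own mean.

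Apart from single arrays left out, lists that stayed called but moved by over 1.5 times were as follows. With the granulocyte covariate, oxidative phosphorylation was -0.303, mitochondrial ribosome -0.183 (camera adjusted p = 0.0347), mitosis 0.0980, cycle exit 0.224 and erythroid factors 0.202. Without both arrays numbered 3, E2F targets were 0.117, cycle exit 0.297 and erythroid factors 0.0636. Array weights gave cycle exit 0.261 and erythroid factors 0.0648. Cycle exit was 0.0763 without a filter and 0.219 with a strict filter, and B cell markers were -0.152 and -0.564. Erythroid factors were 0.158 without quantile normalization and with arrays centred on their medians.

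With an estimated correlation all 16 called lists lost their call at unchanged medians: E2F 0.184, mitosis 0.205, cycle exit 0.144, p53 0.390, oxidative phosphorylation -0.466, tricarboxylic acid cycle -0.326, fatty acid oxidation -0.334, mitochondrial ribosome -0.327, heme -0.255, erythroid factors 0.104, autophagy -0.202, ribosomal proteins -0.260, immediate early 0.175, granulocyte -0.517, macrophage -0.318 and B cell -0.349.

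Leaving out 1 array at a time gave E2f3 -0.896 to 0.0535, Rbl2 -0.292 to 0.0721, Gata1 -0.116 to 0.191, Epor -0.934 to 0.686, Rbl1 -0.565 to 0.374, E2f4 -0.228 to 0.365, Nrf1 -0.102 to 0.0538, Hba-x -0.203 to 0.0282, Hbb-y -0.271 to 0.447 and Gp5 -0.0200 to 0.498. Of 128 named genes, 61 changed sign or moved by over 1.5 times without 1 of the arrays, among them Epx (-1.26 to -0.0585), Vcam1 (-1.55 to -0.275), Cybb (-1.69 to -0.510) and Hbb-bh1 (-1.04 to -0.0456). Called lists spanned 0.0687 to 0.357 (E2F; lost without control 3), 0.0729 to 0.366 (mitosis; control 3 at 0.0756 or Rb-null 1), 0.0723 to 0.157 (cycle exit; Rb-null 2 at 0.0980), -0.510 to -0.164 (tricarboxylic acid cycle; control 2 at -0.238 or Rb-null 3), -0.330 to -0.226 (fatty acid oxidation; the same arrays, at -0.293 and -0.233), -0.297 to -0.167 (heme; the same arrays, control 2 at -0.202), -0.0137 to 0.180 (erythroid factors, negative without Rb-null 3; control 1 at 0.0468 or Rb-null 2), -0.186 to -0.119 (autophagy; any array but Rb-null 3), 0.0475 to 0.379 (immediate early; control 3 or Rb-null 1 at 0.0940), -0.902 to -0.0731 (granulocyte; Rb-null 1), -0.518 to -0.0303 (macrophage; control 3 or Rb-null 1 at -0.167) and -0.498 to -0.0929 (B cell; Rb-null 1). Lists that stayed called and moved by over 1.5 times were p53 (Rb-null 3, 0.245), mitochondrial ribosome (control 2, -0.192), ribosomal proteins (control 2, -0.172, and Rb-null 2, -0.441), E2F (control 1, 0.324, control 2, 0.357, and Rb-null 3, 0.312), mitosis (Rb-null 3, 0.366), cycle exit (Rb-null 1, 0.0723), tricarboxylic acid cycle (control 3, -0.490, and Rb-null 2, -0.510), autophagy (Rb-null 3, -0.119), immediate early (control 1, 0.364, Rb-null 2, 0.379, and Rb-null 3, 0.0636), granulocyte (control 2, -0.282, and Rb-null 2, -0.902), macrophage (control 1, -0.518, and control 2, -0.483) and B cell (control 3, -0.165). Uncalled lists spanned -0.0898 to 0.105 (regulators of mitochondrial biogenesis), -0.129 to 0.00780 (globins), -0.0407 to 0.0529 (red cell membrane), -0.0569 to 0.0457 (progenitor), -0.163 to 0.104 (glycolysis), -0.183 to 0.0772 (interferon), -0.144 to 0.253 (T and NK) and -0.281 to 0.0864 (megakaryocyte).

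Signal over background limits dim genes such as Ppargc1b, at most 10.8 on any array. The small number of arrays, unknown animal numbers, the unstated making of the values and the replicate 3 arrays limit the rest. Granulocyte RNA was present on every array, with S100a8 at 9111 to 12488, so the values do not come from erythroid cells alone.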

Other observations

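The tests on ribosomal proteins, the authors' scaling, immediate early genes and swapped labels, the granulocyte covariate and both added gene lists were chosen after the results were seen. Sex-linked genes gave Eif2s3y signal of 239, 222 and 45.7 in control arrays 1, 2 and 3 and 130, 157 and 30.0 in Rb-null arrays 1, 2 and 3, and the brightest Xist probe set read 42.3 to 57.5. A gap of over 2 log2 units that crossed between pairs 1 and 2 was present in 4 of 13232 genes. Epor read 2221, 266 and 609 in controls and 248, 2228 and 558 in Rb-null arrays. Diras1, chosen after its values were seen, read 4596, 35 and 71 in controls and 87, 4855 and 32 in Rb-null arrays.

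A set of 6 genes of the amino acid and integrated stress response was picked by hand after the gene table was seen, without a test for enrichment. Besides Ddit3 and Ddit4, it held Cebpg at 1.40 (SE 0.25), the transporter subunits Slc3a2 at 1.34 (SE 0.33) and Slc7a5 at 1.10 (SE 0.43), and Eif4ebp1 at 1.49 (SE 0.32). A hypothesis is that this response may be raised in Rb-null cells. A further 30 genes of the response that had not led the table had a median of 0.385 (95% interval 0.0997 to 0.586), with 24 positive. Of the 30, 5 had a limma unadjusted p under 0.05, such as Trib3 at 1.69 (SE 0.42) and Mthfd2 at 1.64 (SE 0.40). Others of the 30 lay near 0, such as Chac1 at 0.05 (SE 0.29), Psat1 at -0.01 (SE 0.59) and Phgdh at -0.01 (SE 0.30). With the replicate block 14 rose at a limma unadjusted p under 0.05, as did 1028 of all 13232 genes. The lower bound of the median's interval lies just under the 0.1 set for the test, so the hypothesis stays open. The other added list, of glucocorticoid and FoxO response genes, had a median of 0.247 over 13 members (95% interval 0.0618 to 0.584), 10 of them positive. Per1 had 1.68 (SE 0.42), and 2 members had a limma unadjusted p under 0.05. The negative members were Fkbp5 at -0.47 (SE 0.40), Sgk1 at -0.37 (SE 0.59) and Cited2 at -0.22 (SE 0.40). The 13 members include Irs2, which had led the gene table and was not set apart here.

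Oxidative phosphorylation genes were lower in Rb-null arrays (median -0.466). With the granulocyte marker level as a covariate the median was -0.303 (95% interval -0.380 to -0.242), so the marker level did not account for the whole fall in that fit. The interval is over genes and leaves out the spread between the 6 arrays. Pair medians were -0.361, -0.449 and -0.554 for this list. For granulocyte markers they were -0.761, -0.0329 and -0.721, so the falls did not follow each other across pairs. With the covariate 9 lists lost their call. The granulocyte markers are 1 of the 9, and lost it by construction, since the covariate is their own mean. A fall of this size in all transcripts of like expression is argued against, as random lists of them had a lower bound of -0.110. Random lists take no account of genes that move together, and the estimated correlation in this list was 0.216. Lists such as macrophage and B cell markers also lay below their own lower bounds, while others, such as apoptosis and globins, did not. The bound therefore does not set this list apart from other groups of related genes. Ribosomal protein genes were lower by less, with a difference of medians of -0.206 (95% interval -0.336 to -0.0702). Scaling of whole arrays by the authors could not be decided, since the deposited values already carry any such scaling. On those values without normalization the median was -0.450, and the lower bound of random lists of like expression was -0.0748. The list median thus lay below that of random genes of like expression, with the same limit for genes that move together. Whether the list fell in absolute amount cannot be told. How probes were summarised is not given in the sources used here and was not tested. RNA quality stays open too, since the actin 3' to 5' ratio was lower in Rb-null arrays in each pair, and its effect on these genes was not tested, and the genotype named by the design remains a possible explanation.

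The rise of p53 targets was set against the same granulocyte covariate, which left a median of 0.338 (95% interval 0.101 to 0.722), its lower bound barely above the 0.1 set for the test. Stress from handling stays open, since immediate early genes had a median of 0.250 and differed from p53 targets by -0.141 (95% interval -0.891 to 0.294). RNA quality was not tested for p53 targets, and the actin 3' to 5' ratio was lower in Rb-null arrays in each pair. The Rb-null genotype may also underlie the rise, and was not tested apart from the labels.

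Rb1 signal was higher in arrays labelled Rb-null. A swap of the labels between groups would place E2F targets lower in those arrays, but the lowest pair median was 0.0365 (95% interval -0.0401 to 0.197), which does not exclude 0. The other pairs had 0.244 and 0.418. Probe sets outside the floxed part would read a transcript that is still made, which was not tested.

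The 10 splits of the 6 arrays into groups of 3 are too few for a share under 0.05. At adjusted p under 0.05 the real count was 0, which all 10 splits reach whatever the data, so this count decides nothing; the highest other was 2. At unadjusted p under 0.05, 6 splits, the real split among them, gave at least the real 537. The highest other was 1813, from the split that put control 1, control 2 and Rb-null 2 together. That split separates both arrays numbered 3 from 3 of the other 4, which points to a structure of the samples, and with the block the real value was 2237. Among the other 3 splits that part every pair, the highest was 70. For lists called by camera 1 split, the real split, gave 16, with a highest other of 13. Among the 4 splits that part all pairs, 1, the real split, gave 2237 genes with the block, against a highest other of 264.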
